A study of Mus musculus with 15 samples.

How the data were processed

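Total RNA from 15 mouse samples was measured on Illumina bead arrays, 1 array per sample, in 5 groups of 3. Per the labels' protocols, biotin-labelled RNA was prepared with the Ambion MessageAmp kit. The scanner software and its settings are not given in the sources used here. Per the labels, 6 pro-B arrays lay on slide 1, 6 on slide 2 and the 3 DN3 arrays on slide 3. The series text speaks of 3 batches of cultured cells. P-values of the main fit rest on the spread between the arrays of those cultures, pooled over the groups. That fit has no term for replicate pairs, so the spread includes differences between batches and in array quality. The number of arrays limits the precision.

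The deposited scanner table holds a linear intensity and a detection value for each of 45263 probes on each array. The intensities were not normalised between arrays. From the values, a background had been subtracted on the 12 pro-B arrays, where 33.2 to 39.9% of probes lay below 0, and not on the 3 DN3 arrays, whose lowest value was 39.6. The deposited detection value is a fraction from 0 to 1 that rises with the signal, so 1 minus it was used as the detection p. The deposited series matrix holds a score per probe. Set against the scanner table, each score was the linear intensity centred on the probe's mean over the 15 arrays and divided by its SD (correlation 1 for each probe), with no step between arrays. The scores therefore hold no log2 fold changes and served as an alternative only. No 2 arrays shared more than 0.703% of their signals.

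Depth differed between arrays. Control replicate 3 had a mean signal of 187 and 11473 detected probes, the other pro-B arrays 445 to 769 and 14946 to 16422, and the DN3 arrays 156 to 178 and 14448 to 14767. Control replicate 3 correlated at 0.917 to 0.919 with the other control arrays, and it was kept in the fit.

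Intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background by detection p, added an offset of 16, quantile normalised the arrays and took log2. The pro-B arrays were normalised without the DN3 arrays, and all 15 arrays together for the DN3 comparison. A probe was kept when its detection p was under 0.05 on at least 3 of the arrays fitted, which left 17719 probes (18843 with all arrays). The gene table gives 1 symbol to 34874 probes and several to 18, and does not list 10371. Of the kept pro-B probes, 14897 had 1 symbol and 2822 were unnamed here. Each gene was represented by its kept probe with the highest mean, which gave 9687 genes for the pro-B comparisons and 10290 for the DN3 comparison. Of 542 genes in the fixed lists, 56 had no named probe, among them Trp53, Bax, Cd79a and Mki67, and these 56 were not analysed here. The RefSeq table of assembly GRCm38.p6 was used for names and neighbours only, with no coordinates.

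A linear model with 1 mean per group was fitted over the 12 pro-B arrays (lmFit and eBayes), so that the 4 groups share 1 estimate of the spread, and 7 comparisons were tested. These were the labelled deficient arrays against their controls without Bcl2 and with Bcl2, the mean of those effects, their difference (the interaction), Bcl2 arrays against arrays without Bcl2 in the control state and in the labelled deficient state, and DN3 against control pro-B arrays. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Errors are standard errors of the log2 fold change, or SD for group means, with n = 3 arrays per group. An exact permutation test of 3 against 3 arrays cannot go below a two-sided p of 0.1, so none was used for single genes. Where a gene was below background on every array of 1 group, its fold is a bound. It sets the bright group's mean against the dim group's mean of, per array, the lowest signal among detected probes or the probe's own signal if higher, and is written "at least N-fold".

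The design, the alternatives, 24 gene lists and the rule for the genes named were fixed before the data were examined. The rule takes Bcl11a, Bcl11b, Bcl2 and Trp53 throughout. In the single Bcl11a comparisons and their mean it takes the 8 highest and 8 lowest log2 fold changes among passing genes whose arrays do not overlap between the groups, and 5 each in the other comparisons. If none passes, the 4 genes with the smallest p are taken and reported as not passing. It adds up to 4 members per list with the smallest p in the single Bcl11a comparisons and their mean, and of the T cell and early B cell lists in the DN3 comparison. The lists came from general knowledge, not from these samples. They cover p53 target genes, the BCL2 family and caspases, early B cell genes, later B cell genes, stem and multipotent progenitor genes, neutrophil and monocyte genes, plasmacytoid dendritic cell genes, conventional dendritic cell genes, T cell genes, NK and innate lymphoid genes, erythroid and megakaryocyte genes, embryonic globin genes, basophil and mast cell genes, stromal and endothelial genes, S phase genes, G2 and M phase genes, interferon response genes, sterol synthesis genes, IL-7 receptor and STAT5 target genes, integrated stress response genes, immediate early and heat shock genes, cytosolic ribosomal protein genes, mitochondrial respiratory chain genes, and Y-linked and Xist genes as a check of sex. The embryonic globin genes had 0 measured members, which left 23 lists. Each was tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Adjusted p of lists are over the 23 lists of a comparison.

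The model fit, list test and counting were run on simulated log2 values with 200 genes changed among the real genes. Each gene had its own spread, with independent noise that was equal on all arrays. The simulation held no dim array, no replicate pairs and no correlation between genes. Normalisation, filter and choice of probe were not tested. For the labelled deficient arrays without Bcl2, 4.48% of genes changed 1.5-fold, 46.3% changed 2-fold and 86.4% changed 4-fold were recovered among 9687 genes. With Bcl2 these shares were 14.9%, 59.7% and 86.4%, for the mean effect 29.9%, 77.6% and 98.5%, and for the difference 1.49%, 16.4% and 69.7%. For Bcl2 in the control state they were 11.9%, 41.8% and 87.9%, for Bcl2 in the labelled deficient state 10.4%, 37.3% and 80.3%, and for DN3 10.4%, 46.3% and 93.9% of 10290 genes. Each share rests on 66 or 67 changed genes. With equal noise and group sizes, comparisons of a pro-B group with another differ in these shares only through the genes and noise drawn. Such gaps do not show that changes were harder to recover without Bcl2. False calls numbered 2 to 7 per comparison in this setting, and shares and false calls on the real arrays can differ.

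Whether replicate numbers pair the arrays was checked by the correlation, across genes, of deviations from group means. Without Bcl2 the same-numbered labelled deficient and control arrays correlated at 0.354, 0.351 and 0.307, and with Bcl2 at 0.390, 0.331 and 0.229. Without Bcl2 they also shared the pattern of Xist and Eif2s3y. With Bcl2 every array had the male pattern, so it cannot show pairing there. The numbers were taken to pair the arrays within each Bcl2 background. Same-numbered arrays there also share the slide, so the correlations alone do not show a shared culture. Between backgrounds the correlations were 0.300, -0.00 and 0.322 in the control state and 0.0433, -0.126 and 0.104 in the labelled deficient state. These were uneven, and replicates 1 and 3 differed in sex between backgrounds, so numbers were not taken to pair arrays there.

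The alternatives fixed at the start were normexp with an offset of 50, no background correction, centring on the 75th percentile, cyclic loess, no filter and a strict filter on detection, every detected probe, the series matrix values, the slide as a block, the replicate block, only the groups compared, all arrays normalised together, eBayes with trend and robust, array weights, each slide alone, and each array left out. On slide 1 the Bcl2 groups have 1 array each, and on slide 2 the groups without Bcl2, so the spread within slide 1 comes from the groups without Bcl2 and within slide 2 from the Bcl2 groups. Alternatives chosen after seeing the data were the replicate block within each Bcl2 background, the sex of the mice as a term, and leaving control replicate 3 out of the shared spread. No column of per-sample values was left unused.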

Results

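Gene expression was measured in pro-B cells, the earliest committed B cell precursors, grown from mouse bone marrow for 10 days with IL-7, Flt3 ligand and SCF. The labels give 4 pro-B groups of 3 arrays each. These are Bcl11a-deficient, control, Bcl2-rescued Bcl11a-deficient, and control cells that overexpress Bcl2, a protein that blocks cell death. The sample titles give OHT to both deficient groups and to neither control group. OHT commonly stands for 4-hydroxytamoxifen, a drug used to switch on gene deletion, so the effect of the drug and that of the deletion cannot be told apart in any comparison here. A further 3 arrays hold DN3 cells, an early T cell stage, labelled Bcl11bCKO. Each array carried 45263 probes, of which 11473 to 16422 were above background, with control replicate 3 the lowest.

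**Figure D1:**
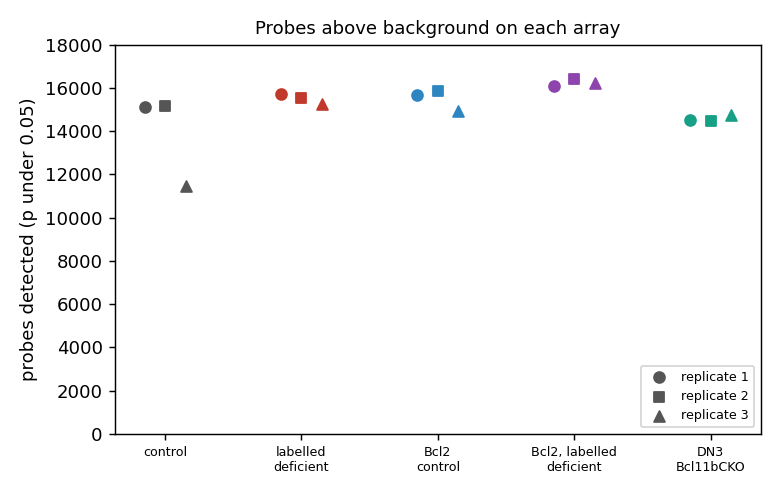
Number of probes above background (detection p under 0.05) on each of the 15 arrays, 1 symbol per array and 3 replicates per group. Control replicate 3 had 11473 detected probes, and each of the other 14 arrays had 14448 or more.

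Bcl11a, a zinc finger transcription factor needed for B cell development, went against the label on the arrays without Bcl2. Its brightest probe (ILMN_2712044) read 11.34, 11.65 and 11.48 on the arrays labelled Bcl11a-deficient and 9.57, 9.30 and 10.00 on the control arrays, in normalised log2 intensity. The difference was 1.87 ± 0.20 (log2 fold change ± SE, limma adjusted p = 0.0033), higher in 3 of 3 labelled deficient arrays. The call was lost in 3 of 22 alternatives, the series matrix aside, among them the replicate block within each Bcl2 background. With Bcl2 the same probe read 9.87, 10.26 and 10.30 on the labelled deficient arrays and 10.84, 11.02 and 10.95 on the Bcl2 control arrays, a difference of -0.79 ± 0.20 (adjusted p = 0.012). Averaged over both backgrounds this Bcl11a probe differed by 0.54 ± 0.14 (adjusted p = 0.023), a mean of effects of opposite sign, and the call was lost in 7 of 27 alternatives, the series matrix aside. It was lost within slide 1 (0.135) and slide 2 (0.068), and without Bcl2 control replicate 1 (0.060), labelled deficient replicate 2 (0.064) or 3 (0.051), or Bcl2-rescued replicate 2 (0.062) or 3 (0.064). It was also lost with the series matrix (0.164). A second probe (ILMN_1257463) gave -0.25 ± 0.44 without Bcl2 and -0.92 ± 0.44 with it, with limma adjusted p of 0.875 and 0.175 over all detected probes. Its sign without Bcl2 rests on control replicate 3, which read 10.99 against 9.02 and 9.23 on the other control arrays, and without that array the difference was 0.37 ± 0.25 (adjusted p = 0.73). The probe ILMN_1234185 was below background on all 12 arrays. The labels do not say which part of Bcl11a was deleted, so it is unknown whether any probe reads that part. For this reason these arrays are called "labelled deficient" throughout, and each direction below is relative to that label only.

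The brightest mouse Bcl2 probe (ILMN_1249366) did not pass in any comparison among the pro-B arrays as fitted, though it did as lower with Bcl2 under some alternatives. Its log2 fold changes for Bcl2 arrays against arrays without Bcl2 were -0.83 ± 0.40 in the control state (limma adjusted p = 0.23) and -0.82 ± 0.40 in the labelled deficient state (adjusted p = 0.13). Over the alternatives the adjusted p of Bcl2 ran from 0.022 to 0.76 in the control state, passing with array weights and without control replicate 3 (0.025), and from 0.017 to 0.50 in the labelled deficient state. The other 3 detected Bcl2 probes gave 0.72 ± 0.46, 0.03 ± 0.33 and -0.44 ± 0.57 in the control state and 0.08 ± 0.46, -0.05 ± 0.33 and -0.86 ± 0.57 in the labelled deficient state, and none passed. Between the labelled deficient and control arrays the brightest gave 0.04 ± 0.40 without added Bcl2 and 0.05 ± 0.40 with it (adjusted p of 0.98 and 0.95). It is not given in the sources used here whether the added Bcl2 carries the sequence these probes read. Bcl11b, the relative of Bcl11a that acts in T cells, was below background with each of its 4 probes on all 12 pro-B arrays. Trp53 was not analysed here.

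**Figure D2:**
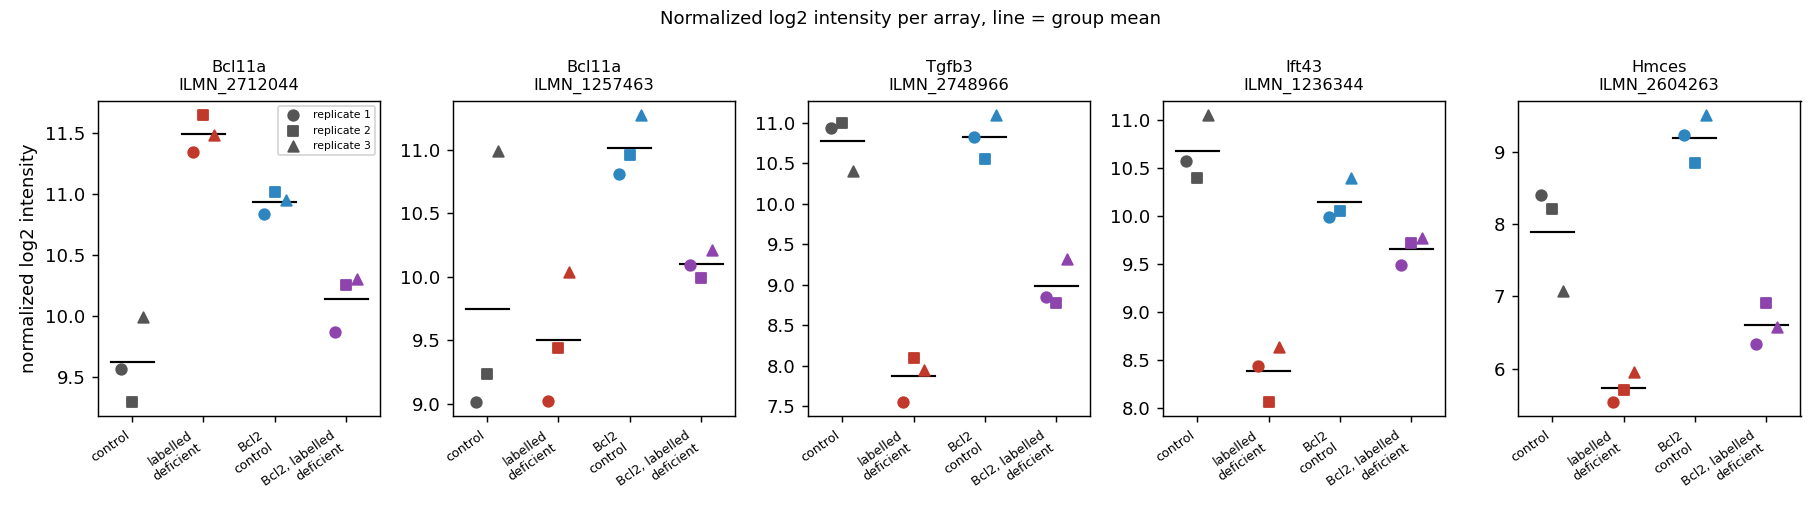
Normalised log2 intensity of 5 probes on each pro-B array, with 1 symbol per array, replicates 1 to 3 by shape, and the mean of 3 arrays as a line. The first Bcl11a probe lies higher on the labelled deficient arrays without Bcl2 (mean 11.49 against 9.62) and lower on those with Bcl2 (10.14 against 10.93), while Tgfb3 lies lower on the labelled deficient arrays in both backgrounds.

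The first comparison asks how pro-B cells without added Bcl2 differ when labelled Bcl11a-deficient. Without Bcl2, 2 neighbouring genes fell on the labelled deficient arrays. Tgfb3, which encodes a transforming growth factor, fell by 2.91 ± 0.23 on the log2 scale (mean 7.87 ± 0.28 against 10.78 ± 0.32, SD, n = 3, adjusted p = 0.00057). Ift43, a component of the transport system inside cilia, fell by 2.29 ± 0.21 (adjusted p = 0.0014). It is the next gene after Tgfb3 in the gene table, while the genes on the other side gave -0.11 for Ttll5 and 0.07 for Erg28 (adjusted p of 0.88 and 0.91). Hmces, a protein that shields damaged sites in single-stranded DNA, did not pass at -2.16 ± 0.32 (adjusted p = 0.057). Pim2, a survival kinase induced by cytokines, did not pass either (at least 1.09-fold higher, adjusted p = 0.057). Hmces and Pim2 were singled out after their values were seen.

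In that comparison 3 of 9687 genes passed in limma, 1 higher (Bcl11a) and 2 lower, and 581 had an unadjusted p under 0.05. With no effect a share of 0.05 of all genes would have such a p, so the 581 show no effect by themselves. The count was 375 without labelled deficient replicate 3, and 1225 and 1307 without control replicates 1 and 2. In those last 2 fits the dim control replicate 3 is 1 of the 2 control arrays left. No single member of any list passed. As groups, 5 lists shifted upward in camera. These were the IL-7 receptor and STAT5 target genes (16 measured, median log2 fold change 0.20, or 0.08 with members below background at their bound, adjusted p = 0.031, and 2 members higher when adjusted over the list alone) and, each with adjusted p = 0.046, 4 others. The conventional dendritic cell genes had a median of 0.43 (12 measured), the sterol synthesis genes 0.29 (17), the p53 target genes 0.26 (30, or 0.22 with bounds) and the interferon response genes 0.21 (20, or 0.15 with bounds). Adjusted over the list alone, 1 p53 target gene was higher and the other 3 lists had 0. With an estimated correlation none of the 5 held (adjusted p = 0.28 for the IL-7 receptor list and 0.61 for the others). The S phase genes had a median of -0.08 (22 measured, adjusted p = 0.30) and the G2 and M phase genes one of 0.04 (17 measured, adjusted p = 0.59).

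With the slide as a block 3 genes and 0 lists passed (adjusted p of the 5 lists 0.069 to 0.077). Within slide 1, with 2 arrays per group, limma called 0 genes (479 at an unadjusted p under 0.05), and within slide 2, with 1 array per group and control replicate 3 as the control, 3089. The median of the p53 target genes was 0.29 within slide 1 and -0.17 within slide 2. With only these 6 arrays in the fit limma called 0 genes (245 unadjusted), and with the replicate pairs as a block within each background 2, the call of Bcl11a being lost (adjusted p = 0.053, with a range of 0.00017 to 0.628 over the alternatives). Without control replicate 1 or 2 the count was 5. No list passed without control replicate 1 or labelled deficient replicate 2, and 9 and 8 did without labelled deficient replicate 1 and control replicate 3.

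The same question was asked in cells that overexpress Bcl2, where the labelled deficient arrays showed a broad fall of cell cycle genes. All 22 measured S phase genes fell, with a median log2 fold change of -2.22, among them the replication factor Cdc45 (-3.13 ± 0.16), the helicase subunit Mcm5 (-2.61 ± 0.14) and Tyms, which makes thymidylate (-3.95 ± 0.23). Of 17 G2 and M phase genes 15 fell (median -2.99, or -2.90 with bounds), among them Cdca8 (-3.57 ± 0.17) and Aurka (-2.90 ± 0.15), which act at the spindle and kinetochores, and Cdc20 (-2.85 ± 0.14), which starts anaphase. The 8 largest falls were those of Sapcd2 (-4.34), Pclaf (-4.20), Sgo1 (-4.19), Kif2c (-4.11), Pbk (-4.10), Cdkn3 (-4.06), Kif11 (-4.06) and Mcm10 (-3.95), most of them known for roles in DNA replication or mitosis. For both lists the camera adjusted p (7.0e-24 and 5.9e-18) held with an estimated correlation (adjusted p = 0.00315 for each).

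On the same arrays 13 of 20 interferon response genes rose (median 0.95, or 0.76 with bounds, adjusted p = 1.1e-06, and 0.046 with an estimated correlation), including Ifit3 (3.02 ± 0.24) and the guanylate-binding Gbp2 (2.15 ± 0.20). Of 30 p53 target genes 15 rose and 1 fell (median 0.84, adjusted p = 1.4e-05, but adjusted p = 0.12 with an estimated correlation). The death receptor Fas rose by 2.70 ± 0.28, the costimulatory protein Cd80 was at least 8.72-fold higher, and Mdm2, the negative regulator of p53, rose by 1.22 ± 0.20, while Ckap2, a spindle protein, fell by 2.16 ± 0.29. Of 17 sterol synthesis genes 11 fell (median -1.08, adjusted p = 3.3e-07, but adjusted p = 0.12 with an estimated correlation), among them the enzymes Sqle (-1.96 ± 0.20), Cyp51 (-2.16 ± 0.23) and Fdps (-2.08 ± 0.28). In the BCL2 family and caspase list 4 of 20 rose and 1 fell (median 0.41, or 0.37 with bounds, adjusted p = 0.043, but adjusted p = 0.12 with an estimated correlation). The death-promoting Bcl2l11 (1.96 ± 0.21) and Pmaip1 (1.19 ± 0.24) rose together with the protective Mcl1 (0.99 ± 0.19), and Bok was at least 5.85-fold lower.

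Some genes of dendritic and B lineage cells were higher. Of 12 conventional dendritic cell genes 7 rose (median 1.53, adjusted p = 2.0e-05, and 0.12 with an estimated correlation), and of 18 later B cell genes 10 rose (median 1.29, adjusted p = 3.7e-05, and 0.21 with an estimated correlation). Of each of these lists 7 measured members are also in another list, and both hold class II antigen presentation genes such as H2-Eb1 (2.91 ± 0.49) and Cd74 (2.34 ± 0.44), and Cd86 (2.09 ± 0.19), Id2 (1.73 ± 0.25) and Cd83 (2.24 ± 0.24) also rose. Of 26 early B cell genes 6 rose (median 0.40, adjusted p = 0.011, and 0.21 with an estimated correlation), among them Rag1 (1.93 ± 0.37) and Dntt (1.85 ± 0.28), which act in V(D)J recombination, Foxo1 (1.17 ± 0.18) and the IL-7 receptor chain Il7r (0.84 ± 0.17). Of 17 immediate early and heat shock genes 8 rose (median 0.99, adjusted p = 0.0025, and 0.12 with an estimated correlation), with Jun at 2.04 ± 0.32 and Hspa1a at 1.67 ± 0.23. Smaller falls were seen in the mitochondrial respiratory chain genes (7 of 19, median -0.50, adjusted p = 0.0012, and 0.21 with an estimated correlation), as for Ndufa4 (-0.74 ± 0.15), and the cytosolic ribosomal protein genes (5 of 20, median -0.22, adjusted p = 0.019, and 0.14 with an estimated correlation), as for Rpl4 (-1.54 ± 0.19).

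Large rises with Bcl2 were those of Sln (4.38 ± 0.42), a regulator of the calcium pump in muscle, Espn (at least 11.95-fold), an actin-bundling protein, Grb10 (4.01 ± 0.31), a signalling adaptor, the chemokines Ccl9 (3.89) and Ccl3 (3.64), Lrrc15 (3.83), Ddit4l (3.73) and the homeobox gene Dlx1 (3.71). A second Grb10 probe did not change (0.09 ± 0.25), so the rise rests on 1 of its 2 probes. Tgfb3 fell by 1.84 ± 0.23 (adjusted p = 0.00018) and Hmces by 2.59 ± 0.32 (adjusted p = 0.00014), while Ift43 did not pass (-0.49 ± 0.21, adjusted p = 0.13). On the other side of Tgfb3, Erg28 passed as lower (-0.74, limma adjusted p = 0.0071) and Ttll5 did not pass (-0.57, adjusted p = 0.087). The fall of Ift43 but not of the genes on the other side was thus not seen with Bcl2.

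In this comparison 2426 of 9687 genes passed in limma, 1237 higher and 1189 lower, and 12 of 23 lists. Adjusted over the list alone the counts were 22 lower S phase, 16 lower G2 and M phase, 13 lower sterol synthesis, 16 higher interferon, 19 higher and 2 lower p53 target, 11 higher conventional dendritic cell, 12 higher later B cell, 6 higher early B cell, 10 higher and 1 lower immediate early, 7 lower mitochondrial, 5 lower ribosomal, and 4 higher and 1 lower BCL2 family genes. Of the lists that did not pass, the IL-7 receptor and STAT5 target genes came nearest (adjusted p = 0.081, median 0.69), with 7 of 16 higher, such as Pim2 (2.14 ± 0.20) and Socs3 (2.13 ± 0.21), and 2 lower, such as Gfi1 (-1.31 ± 0.19). The neutrophil and monocyte genes had a median of 0.09 (adjusted p = 0.21), with 4 of 15 higher, such as Fcgr3 (3.25 ± 0.29), Lyz1 (2.22 ± 0.41) and Cebpb (2.10 ± 0.35). Median and adjusted p were -0.00 and 0.31 for T cell genes (mean 0.44), 0.39 and 0.50 for NK and innate lymphoid genes, 0.08 and 0.53 for erythroid and megakaryocyte genes, and 0.10 and 0.60 for plasmacytoid dendritic cell genes. They were 0.08 and 0.64 for stromal and endothelial genes, 0.14 and 0.73 for integrated stress response genes, 0.13 and 0.78 for basophil and mast cell genes, 0.16 and 0.96 for Y-linked and Xist genes, and 0.08 and 0.96 for stem and multipotent progenitor genes. With bounds the medians of the neutrophil, NK, erythroid, basophil and stem lists were 0.

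With the slide as a block 2734 genes and 12 lists passed. Within slide 1, with 1 array per group, 528 genes passed, and within slide 2, with 2 per group, 2755. The medians were -2.23 and -2.20 for S phase genes, -2.90 and -2.98 for G2 and M phase genes, and 0.96 and 0.99 for interferon response genes. With control replicate 3, which is in neither group, left out of the shared spread, 4066 genes passed.

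**Figure D3:**
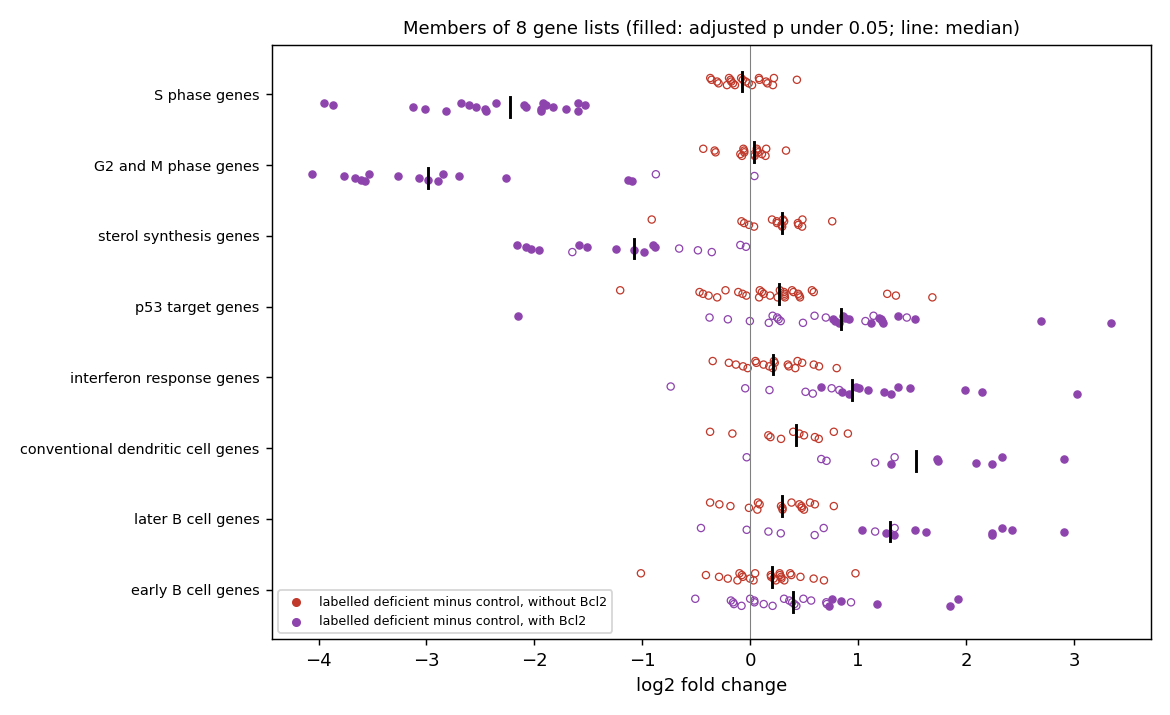
Log2 fold change of each measured member of 8 gene lists, labelled deficient minus control, without Bcl2 (red) and with Bcl2 (purple). Filled symbols have an adjusted p under 0.05 and black lines are medians. S phase genes had a median of -0.08 without Bcl2 and -2.22 with it.

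The mean of both Bcl11a comparisons asks what the backgrounds had in common on average. Arrays of 2 groups do not overlap by chance in 10% of genes. Of all genes, 7.87% met this without Bcl2, 53.2% with Bcl2, and 2.97% in both with the same sign. The share without Bcl2 is no higher than chance, so meeting this condition shows no effect there by itself. Among the 217 passing genes whose arrays did not overlap in either background, Tgfb3 (-2.38 ± 0.17) and Hmces (-2.37 ± 0.23) had the lowest mean effects, with limma adjusted p of 5.5e-06 and 4.2e-05. They were followed by the globins Hbb-bt (-2.37 ± 0.19) and Hbb-bs (-2.22 ± 0.18), near-identical copies whose values are uncertain because 1 probe can read both transcripts, and by the mitosis genes Kif15 (-2.21), Kif2c (-2.15), Cdkn3 (-2.09) and Anln (-2.07). Upward mean effects among them were those of Smagp (2.21), Espn (2.10), Fas (1.98), Cd80 (1.83), Myo7a (1.75), Pim2 (1.73), Traf5 (1.62) and Ski (1.58). Espn and Cd80 were below background on all 6 arrays without Bcl2, Pim2 was on the 3 control arrays without Bcl2, and Smagp on the 6 control arrays of both backgrounds. The sizes for these 4 genes depend on the background level and were not measured, and for Espn and Cd80 the arrays without Bcl2 compare background with background. The mean effects of Ccl3, Sln and other genes were as high, but their arrays did not meet that condition. Of the BCL2 family and caspase genes 3 rose and 1 fell (adjusted p = 0.038, and 0.099 with an estimated correlation).

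A mean effect passed in 1565 genes, 783 higher and 782 lower, and in 12 lists. All 22 S phase genes, 14 of 17 G2 and M phase genes and 6 of 17 sterol synthesis genes fell, and 9 of 20 interferon response, 12 of 30 p53 target and 6 of 16 IL-7 receptor and STAT5 target genes rose (1 of each of the last 2 lists fell). Adjusted over the list alone these counts were 22, 15, 9, 12, 17 and 8. The S phase, G2 and M phase and interferon lists held with an estimated correlation (adjusted p = 0.00325, 0.00325 and 0.0395), while for the sterol list the adjusted p was 0.13 and for the other 2 it was 0.099. Further lists were the conventional dendritic cell (8 of 12 higher), later B cell (8 of 18), immediate early (5 of 17), early B cell (7 of 26) and mitochondrial genes (2 of 19 lower), with adjusted p of 8.0e-06, 2.5e-05, 0.0013, 0.0065 and 0.033, and 0.099, 0.20, 0.099, 0.20 and 0.45 with an estimated correlation. A mean of unequal effects does not show an effect in each background. Between the comparisons, which share no arrays, 1 gene (Tgfb3) fell in both (0.245 expected for independent lists) and 0 rose in both (0.128 expected). They do share the estimate of each gene's spread, so their calls are not independent and the expected numbers are a rough guide. The log2 fold changes correlated across genes at 0.123 (Pearson) and 0.106 (Spearman), genes not being independent replicates. With the slide as a block 1880 genes passed, within slide 1 317 and within slide 2 3354, and without control replicate 3 3038, while 1039 passed without labelled deficient replicate 2. The S phase median was -1.25 within slide 1 and -1.18 within slide 2.

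Whether the effect of the label differed with Bcl2 was tested by the difference between both comparisons. The effect on cell cycle genes was lower with Bcl2 than without it by the largest margins, led by Sapcd2 (-4.42 ± 0.34), Pclaf (-4.32), Sgo1 (-4.07), Pbk (-4.05) and Tk1 (-4.02), a thymidine kinase. All 22 S phase genes (median -2.14) and 13 of 17 G2 and M phase genes (median -3.06) differed. Among the named genes with an upward difference, Grb10 (3.83, and -0.15 with its second probe) was above background on all 12 arrays. Sln (4.24 ± 0.59), Hey1 (4.09), Espn (3.93) and Lrrc15 (3.78) were below background on 4 or more of the 6 arrays without Bcl2, and Espn on the Bcl2 control arrays too, so the sizes of these 4 differences depend on the background level and were not measured. The brightest Bcl11a probe differed by -2.66 ± 0.28 (adjusted p = 0.00013), while the other detected probe gave -0.67 ± 0.62 (adjusted p = 0.57 over all detected probes). Ift43 differed by 1.81 ± 0.30 (adjusted p = 0.0030), while for Tgfb3 the difference did not pass (1.07 ± 0.33, adjusted p = 0.064).

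The difference passed in 1047 genes, 449 higher and 598 lower, and in 10 lists. The S phase and G2 and M phase lists held with an estimated correlation (adjusted p = 0.0025 for each). The sterol synthesis genes (8 of 17 lower, median -1.37) and the interferon response genes (3 of 20 higher, median 0.70) had an adjusted p of 0.091 with an estimated correlation, and the p53 target genes (3 of 30 higher, 1 lower, median 0.65) one of 0.25. Of the other lists, the conventional dendritic cell (4 of 12) and later B cell genes (4 of 18) were higher, as were 2 of 17 immediate early genes, and 2 of 20 ribosomal and 0 of 19 mitochondrial genes were lower (adjusted p = 0.0012, 0.0012, 0.024, 0.026 and 0.00072, and 0.26, 0.36, 0.25, 0.25 and 0.26 with an estimated correlation). The counts adjusted over the list alone were 22 S phase, 15 G2 and M phase, 11 sterol synthesis and 5 mitochondrial genes lower, and 7 interferon and 7 p53 target genes higher (1 p53 target gene lower). With the slide as a block 1268 genes passed, within slide 1 116 and within slide 2 3412. Without control replicate 3 the count was 2018, and it was 656 without Bcl2 control replicate 2, 669 without Bcl2-rescued replicate 1, 687 and 688 without labelled deficient replicates 3 and 1, and 689 without Bcl2-rescued replicate 3.

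Myeloid genes were lower and p53 target genes higher on the Bcl2 control arrays than on the control arrays. These groups differ in Bcl2, partly in sex and in their spread over the slides. Replicate numbers were not taken to pair their arrays, so Bcl2 cannot be told apart from other differences between the mice or cultures. The lysozyme genes Lyz2 (at least 37.8-fold lower) and Lyz1 (-5.99 ± 0.41), the macrophage gene Gpnmb (-5.93 ± 0.73) and the neutrophil enzyme gene Mpo (at least 19.3-fold lower) fell, and 8 of 15 neutrophil and monocyte genes fell while 1 rose (median -1.28, or -1.21 with bounds, adjusted p = 3.8e-09, and 0.063 with an estimated correlation). Of 30 p53 target genes 13 rose and 0 fell (median 0.83, or 0.77 with bounds, adjusted p = 3.8e-09, and 0.063 with an estimated correlation), among them Phlda3 (3.14 ± 0.60), an inhibitor of AKT signalling. Gdpd3 (4.47 ± 0.45), Smoc1 (at least 4.55-fold), Dnali1 (at least 4.48-fold) and Sln (at least 3.41-fold) also rose. Of 17 G2 and M phase genes 8 fell (median -0.68, adjusted p = 2.9e-10, and 0.037 with an estimated correlation). Among them the mitotic kinase gene Plk1 was at least 101-fold lower with its single probe. That probe was below background on all 6 Bcl2 arrays and did not differ with the label there (0.04 ± 0.24). With no second probe, it was not tested whether the transcript fell as the signal did.

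Here 788 genes passed in limma, 415 higher and 373 lower, and 7 lists. Other lists that passed were the S phase (4 of 22 lower, adjusted p = 4.6e-05, and 0.13 with an estimated correlation) and conventional dendritic cell lists (6 of 12 lower, adjusted p = 0.0020, and 0.29 with an estimated correlation). The IL-7 receptor and STAT5 target genes (5 of 16 higher, 1 lower) and the later B cell genes (2 of 18 higher, 7 lower) each had an adjusted p of 0.026, and 0.13 and 0.59 with an estimated correlation. When adjusted over the list alone, 11 neutrophil and monocyte, 12 G2 and M phase and 6 S phase genes were lower and 17 p53 target genes higher. By Xist and Eif2s3y, all 6 Bcl2 arrays came from male mice and 4 of 6 arrays without Bcl2 from female mice. With sex as a term 394 genes and 10 lists passed, and none of the lists held with an estimated correlation. That term rests on replicate 2 of each group, the only male arrays without Bcl2. With the slide as a block 1159 genes and 5 lists passed, within slide 1 25 genes and within slide 2 4069. Slide 1 holds a single Bcl2 control array and slide 2 a single control array, the dim replicate 3, so each count assumes that the lone array varies like the groups with 2 arrays on that slide. The count was 1981 without control replicate 3, and 402, 475 and 386 without Bcl2 control replicates 1, 2 and 3. The medians of the neutrophil and monocyte genes were -2.16 and -1.14 within slides 1 and 2, and of the p53 target genes 0.92 and 0.60.

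In the labelled deficient state, cells with Bcl2 had lower cell cycle and higher p53 target genes than cells without it. Here too, Bcl2 cannot be told apart from other differences between the mice or cultures. All 22 S phase genes (median -2.83) and all 17 G2 and M phase genes (median -3.88) fell. Among cell cycle genes, Cdkn3 (-5.35 ± 0.20), Pclaf (-4.98 ± 0.29) and Kif11 (-4.97 ± 0.26) fell. On the Bcl2 control arrays these genes read 10.79, 11.35 and 10.36. Plk1 was at least 80.1-fold lower, but its single probe was below background on the Bcl2 control arrays too. The signal of that probe thus went with Bcl2 and not with the label. Whether it reads the Plk1 transcript alike in all groups was not tested. Of 30 p53 target genes 23 rose and 2 fell (median 1.497, adjusted p = 3.6e-08, and 0.086 with an estimated correlation). Sln (at least 91.6-fold), Gdpd3 (5.21 ± 0.45), Hey1 (at least 20.4-fold), Clic6 (4.72 ± 0.38) and Pde4c (4.71 ± 0.64) rose, and Mpo was at least 24.3-fold lower. The brightest Bcl11a probe fell by 1.35 ± 0.20 here and rose by 1.31 ± 0.20 with Bcl2 in the control state (adjusted p of 0.00026 and 0.0022). The other detected Bcl11a probe gave 0.60 ± 0.44 and 1.27 ± 0.44 (adjusted p of 0.32 and 0.11 over all detected probes).

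This comparison called 3826 genes, 2065 higher and 1761 lower, and 8 lists. The S phase and G2 and M phase lists held with an estimated correlation (adjusted p = 0.0063 and 0.0061). Of the other lists, 10 of 17 sterol synthesis, 9 of 19 mitochondrial and 10 of 15 neutrophil and monocyte genes fell (2 of the last rose), and 9 of 26 early B cell and 9 of 20 interferon response genes rose (1 of the last fell). Their adjusted p were 4.2e-05, 0.00063, 0.0019, 0.016 and 0.031, and 0.27 for each with an estimated correlation. When adjusted over the list alone, 22 S phase, 17 G2 and M phase, 12 sterol synthesis, 10 mitochondrial and 10 neutrophil and monocyte genes were lower, and 25 p53 target, 8 early B cell and 9 interferon genes higher (2 p53 target, 2 interferon genes lower, 2 neutrophil and monocyte genes higher). With sex as a term 2983 genes and 6 lists passed, without the early B cell and interferon lists. With the slide as a block 4018 genes and 8 lists passed, within slide 1 2911 and within slide 2 3511. The S phase median was -2.56 within slide 1 and -2.94 within slide 2.

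DN3 cells differed from control pro-B cells in T cell and B cell genes, among others. Of 24 T cell genes 20 rose and 1 fell (median 4.36, or 3.85 with undetected genes at their bound), among them Cd3d (at least 428-fold), Cd3e (at least 183-fold) and Trat1 (at least 78.7-fold), parts or partners of the T cell receptor complex. Of 26 early B cell genes 18 fell and 3 rose (median -2.12, or -1.92 with undetected genes at their bound), among them the surrogate light chain genes Igll1 (at least 750-fold lower) and Vpreb1 (at least 304-fold lower), Vpreb3 (-8.57 ± 0.31) and the B cell factor Ebf1 (-5.19 ± 0.17). The T cell receptor segment Trbv13-2 (at least 480-fold), Pdlim4 (8.93 ± 0.23) and Thy1 (8.55 ± 0.43) also rose, and Crhbp (-8.70 ± 0.24) and Chst3 (at least 192-fold lower) fell. Bcl11b was at least 189-fold higher in the cells labelled Bcl11bCKO, Bcl11a at least 12.1-fold lower, and Bcl2 higher by 2.94 ± 0.36. No DN3 arrays of control mice were analysed here and the deleted part of Bcl11b is not given in the sources used here, so the high Bcl11b signal checks no label.

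This comparison called 4646 of 10290 genes, 2146 higher and 2500 lower, and 8 lists. The T cell list held with an estimated correlation (adjusted p = 4.8e-16, and 0.0024 with an estimated correlation). The others did not: early B cell (adjusted p = 2.2e-06, and 0.064 with an estimated correlation), stromal and endothelial (7 of 11 higher, 6.7e-05 and 0.16), NK and innate lymphoid (8 of 10 higher, 0.00048 and 0.16), G2 and M phase (11 of 17 lower, 0.023 and 0.52), integrated stress response (9 of 18 higher, 1 lower, 0.028 and 0.52), later B cell (11 of 18 lower, 2 higher, 0.028 and 0.59) and neutrophil and monocyte genes (9 of 16 lower, 3 higher, 0.033 and 0.52). Counts adjusted over the list alone were 20 higher T cell and 18 lower early B cell genes. The DN3 arrays alone lay on slide 3 and came from another strain, so for any single gene cell type, strain and slide cannot be told apart. Centring on the 75th percentile moved the median of all genes from -0.07 to -0.26 and the share of higher genes among those called from 46.2 to 26.7%, and the integrated stress, later B cell and neutrophil lists then did not pass.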

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

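The interaction and the list tests were fixed before the data were examined. Of the tests of explanations, those on swapped labels and on sex were written down before their results were seen. The other tests of explanations, the splits among them, were chosen afterwards. Directions are relative to the label "Bcl11a-deficient", which also carries OHT.

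The effect of the Bcl11a label differed with Bcl2, by the interaction term, in 1047 genes. In 100 splits of the arrays, of 200 distinct ones, 8 gave as many, the real one included, and the highest other gave 1649. All 7 other splits that kept the Bcl2-rescued arrays apart from the Bcl2 control arrays were as large, while splits that mixed these groups gave at most 1. The count therefore follows the grouping within the Bcl2 background and does not need the real grouping of the arrays without Bcl2. Since few genes changed without Bcl2, regrouping only those arrays leaves most of the difference in place. The splits thus cannot test whether the effects differ, and chance is not excluded for this count.

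Median log2 differences between the effects with and without Bcl2 were -3.06 for G2 and M phase genes, -2.14 for S phase genes, -1.37 for sterol synthesis genes, -0.65 for mitochondrial respiratory chain genes and -0.25 for cytosolic ribosomal protein genes. They were 1.22 for conventional dendritic cell genes, 1.01 for later B cell genes, 0.74 for immediate early and heat shock genes, 0.70 for interferon response genes and 0.65 for p53 target genes. With an estimated correlation only the S phase and G2 and M phase lists passed (adjusted p = 0.00248 for each).

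Single genes with a different effect were Sapcd2 (-4.42), Pclaf (-4.32), Sgo1 (-4.07), Pbk (-4.05), Kif11 (-4.00), Cdkn3 (-3.94), Kif2c (-3.91), Mcm10 (-3.73) and Bcl11a (-2.66). Upward differences were those of Grb10 (3.83, but not with its second probe) and Ift43 (1.81), both above background on all 12 arrays. That of Ift43 reflects a fall of 2.29 without Bcl2 beside -0.49 with Bcl2, which did not pass. Fitted differences of Sln (4.24), Espn (3.93), Lrrc15 (3.78), Ccl9 (3.52), Ddit4l (3.13) and Dlx1 (3.08) depend on the background level, since Sln was below background on all 6 arrays without Bcl2, Espn on these and on the Bcl2 control arrays, Lrrc15, Ddit4l and Dlx1 on 3 to 5 of the 6, and Ccl9 and Dlx1 on 2 of 3 Bcl2 control arrays. Beside these, of 149 other named list genes 55 differed, 27 upward and 28 downward. Among 2822 probes without a gene name, 545 passed with Bcl2. Without Bcl2 1 did, ILMN_1218006 (-1.84, and -0.38 with Bcl2, adjusted p = 0.24).

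The first pattern weighed is the brighter Bcl11a probe on the labelled deficient arrays without Bcl2. The genes compared were those called with Bcl2 that had an unadjusted limma p under 0.05 without it, Bcl11a left out. Of these, 78.0% (124 of 159) had the same sign in both Bcl11a comparisons, which argues against labels swapped without Bcl2 alone. A swap in both backgrounds would also give the same signs, so it is not tested. These genes are not independent, and over all genes the log2 fold changes correlated at 0.123 (Pearson). The dim control replicate 3 as the cause is argued against too, since the log2 fold change was 2.05 without it (adjusted p = 0.00056, with 0.00017 to 0.628 over the alternatives). A signal particular to 1 probe remains a candidate explanation, since the other detected probe gave -0.25, a difference of 2.11 (SE 0.48), and 0.37 without control replicate 3, a difference of 1.68 (SE 0.31). Whether the deletion, OHT or a transcript read by that probe alone raised it stays open, and no biological explanation was tested.

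The second pattern is the large number of genes changed with Bcl2 and the few without. That control replicate 3 hides changes without Bcl2 is argued against, since 4 genes passed without it. Cells that escaped the deletion cannot be told apart from a true lack of response, because OHT and deletion coincide. The S phase median of -0.077 lay above the -1.65 predicted from Tgfb3, with 0 of 22 genes at or below their prediction, but Tgfb3 could respond to OHT rather than to the deletion. Added Bcl2 itself, which the design names, stays among the open explanations.

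The third pattern is the lower level of neutrophil and monocyte genes with Bcl2 in the control state. With sex as a term the median was -1.39 (camera adjusted p = 2.5e-09, and 0.065 with an estimated correlation) beside -1.28 without it (0.063 with an estimated correlation). This argues against sex of the mice as the whole cause, within a limit. All Bcl2 arrays were male, and without Bcl2 only replicate 2 of each group was. The sex term therefore rests on those arrays and cannot be told apart from replicate 2. Other cell types in the cultures without Bcl2, and other differences between the mice or cultures, stay open and untested. That 80% of the members detected on all control arrays (8 of 10) were lower with Bcl2 restates the pattern and decides nothing. Members with bright probes included Lyz1 (13.02 against 7.03) and Lyz2 (11.04 against 5.05). An effect of Bcl2 on these genes within pro-B cells stays open, as does any sorting of the cells, which is not given in the sources used here.

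For the mean effect, 4 of 100 splits gave as many genes as the real 1565, the real one included, and the highest other gave 1924. These splits ignore the replicate pairs. Of the 10 that part as many pairs the highest other gave 1348, and 10 are too few for a share under 0.05, so chance is not excluded. The 3 others as large kept the Bcl2-rescued arrays apart from the Bcl2 control arrays, and the highest of those that mixed these groups gave 1. In the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real and highest other counts were 3 and 11 without Bcl2 (4 splits as large), 2426 and 0 with Bcl2, 788 and 0 for Bcl2 in the control state, 3826 and 0 for Bcl2 in the labelled deficient state, and 4646 and 68 for DN3 (1 split as large in each). Without Bcl2 the split with 11 set control replicates 1 and 3 with labelled deficient replicate 1, all female, against the rest, which include the female labelled deficient replicate 3, and the 3 other splits that part all replicate pairs gave 0.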

How the results depend on the processing

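The sex term, the replicate block within each Bcl2 background and control replicate 3 left out of the shared spread were chosen after the data were seen. Over all alternatives, named genes kept their direction and side of the threshold in 3391 results, lost the call in 146, gained it in 26 and reversed in 25. Results of lists called at first kept the call in 794, lost it in 140 and turned in 3. Lists not called at first are not in these totals, and some gained a call, as with fry in the comparison with Bcl2 (15 lists, with 12 of 12 kept) and without Bcl2 when labelled deficient replicate 1 was left out (9 lists, with 5 of 5 kept). The cause was not tested unless given.

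Counts of genes without Bcl2 (3) were 14 with no background correction, 5 with the strict filter, 8 with array weights, 0 with the series matrix (limma, 477 unadjusted), 0 with only the groups compared (245), 0 within slide 1 (479), 3089 within slide 2, and 3 to 5 with 1 array left out. With Bcl2 (2426) they were 649, 4054 and 4475 with the series matrix, only the groups compared and array weights, 528 within slide 1, and 4066 with control replicate 3 out of the shared spread. For the mean (1565) the series matrix gave 0 (2180 unadjusted), weights 3223, slides 1 and 2 317 and 3354, and arrays left out 1039 to 3038. For the difference (1047) these were 0 (1064 unadjusted), 2373, 116 and 3412, and 656 to 2018. For Bcl2 in the control state (788) they were 0 (913 unadjusted), 2062, 25 and 4069, and 386 to 1981, with 169 for only the groups compared and 394 with the sex term. The series matrix gave 1822 for Bcl2 in the labelled deficient state (3826), and only the groups compared 2686 for DN3 (4646). Series matrix scores are linear, and a slide holds fewer arrays.

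Lists called without Bcl2 (5) were 0 with an estimated correlation, 0 with fry, 0 with the slide as a block, 2 with the series matrix, 3 with 75th percentile centring and 0 to 9 with 1 array left out. An estimated correlation left 3 with Bcl2, 3 for the mean, 2 for the difference, 1 and 2 for Bcl2 in the control and labelled deficient states (0 and 3 with the sex term) and 1 for DN3. With fry 15 passed for Bcl2 in the labelled deficient state and 13 for DN3, and 5 to 8 for DN3 with 1 array left out. The direction turned with the series matrix for p53 target genes without Bcl2 (adjusted p = 0.234) and for the integrated stress (0.905) and neutrophil lists (0.684) in DN3.

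With the replicate block the counts of genes were 4, 2512, 1629, 1066, 822, 4015 and 4786, in the order of the report, and those of lists 5, 12, 12, 10, 7, 8 and 8. With the replicate block within each background they were 2, 2625, 1761 and 1189 genes in the first 4 comparisons.

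Bcl2 passed as lower on Bcl2 arrays in the control state with array weights (adjusted p = 0.022) and without control replicate 3 (0.025). In the labelled deficient state it did so with array weights (0.017), only the groups compared (0.017), the replicate block (0.020), within slide 1 (0.038) and with control replicate 3 left out of the shared spread (0.040). In the Bcl11a comparisons, where it did not pass, Bcl2 turned negative under some alternatives. Without added Bcl2 it was -0.014 with cyclic loess, -0.37 with weights, -0.15 within slide 1 and -0.40 to 0.28 with 1 array left out. With added Bcl2 it was -0.0016 with the series matrix, -0.12 with weights, -0.21 within slide 1 and -0.33 to 0.25. The mean was -0.25 with weights, -0.18 within slide 1 and -0.17 to 0.17. The difference was -0.17 with 75th percentile centring, -0.39 with the series matrix, -0.058 and -0.23 within slides 1 and 2 and -0.37 to 0.45.

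Signal over background limits control replicate 3 most, with 11473 probes detected. Changes in genes below background on a whole group are bounds. DN3 has no value within a slide, because slide 3 holds that group alone.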

Other observations

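The values of this part were chosen after they were seen. Plk1, read by 1 probe (ILMN_1255053), had means of 12.03 and 12.46 on the labelled deficient and control arrays without Bcl2 and of 5.19 and 5.15 on those with Bcl2, where it was below background on all 6 arrays.

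Beyond the lysozymes, Mpo (10.07 against 4.90), S100a8 (9.12 against 4.88), Ctsg (7.34 against 4.95) and Elane (7.04 against 5.66) were lower on Bcl2 control than on control arrays, while Gfi1 rose by 0.74 (adjusted p = 0.039). Fcgr3 (0.10) and Cebpb (-0.10) did not pass (adjusted p of 0.88 and 0.89).

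By Xist and Eif2s3y, labelled deficient and control replicates 1 and 3 were female and the 8 other pro-B arrays male. Bcl2-rescued replicate 1 had Xist above background (5.92) beside Eif2s3y (8.60).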
